A study of Triticum aestivum with 45 samples.

How the data were processed

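The deposited values were estimated counts and TPM per transcript for 45 libraries. By the submitters' processing notes, libraries were made with a TruSeq RNA kit, reads were called with CASAVA, trimmed with Trimmomatic, aligned with STAR and quantified with RSEM 1.3.3; the genome build and annotation are not given in the sources used here. The growth chamber was kept at 21 ± 1 °C with light for 16 h a day, and meiocytes were isolated with the MioCapture method. The estimated counts of 346908 transcripts, of which 59.6% of nonzero values lay within 0.005 of a whole number, were summed to 314690 genes and rounded. TPM was used only as an alternative scale for subgenome shares and for the scan along chromosomes.

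Identifiers ending in LC were read as low-confidence genes and those beginning with MSTRG as assembled loci; whether an assembled locus is noncoding is not given. Chromosomes and gene order came from the identifiers, in separate series for high-confidence and low-confidence genes. Assembled loci have no chromosome, and 9449 reference genes were unplaced. None of the identifiers matched the gene table at hand, so no gene names or positions are given, and lists of genes by product name, planned for camera and fry, could not be used. Gene classes, subgenomes and chromosomes, 27 sets per comparison, were tested in their place with camera, and fry was not run.

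Counts were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood tests, Benjamini-Hochberg adjusted p under 0.05). The 21 meiocyte libraries were fitted together for stages, the 33 Chinese Spring libraries for meiocytes against tissues and tissues against each other, the 6 libraries of each tissue for ph1b, and 24 libraries for the interaction. The stage comparisons shared libraries, as did the comparisons with each tissue, so their results are not independent. Genes counted as higher in meiocytes than in all 4 tissues had to be at least 2-fold higher in meiocytes than in each. DESeq2 1.42.0 and limma 3.58.1 were used as named in the text. Shares of counts were compared by exact permutation tests, two-sided, in SciPy 1.17.1 with Benjamini-Hochberg adjustment over 39 tests. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. A fold against a group with 0 counts was computed against a floor of 3 counts over the group and covers counting error only.

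Genes were named by a rule fixed in advance. It took up to 2 that rose and 2 that fell per comparison with the largest fold among those with adjusted p under 0.05, no overlap between libraries and at least 10 CPM in the higher group. It added TraesCS5B02G255100, the 5 lost 5B genes with the highest CPM in Chinese Spring and the ends of each stretch. For the scan along chromosomes, genes with at least 1 CPM were ordered by number, and the median over tissues of the log2 ratio of ph1b to Chinese Spring was smoothed by a running median over 25 genes. A stretch had at least 15 genes under -1 or over 0.4. Single libraries were also read in 1298 bins of 50 high-confidence genes, each the median log2 ratio with 0.5 CPM added, called lost under -2 and raised over 0.5; this reading was chosen after the data were seen. Library totals ran from 1250555 to 26844831 counts, so meiocyte values rest on the fewest counts. Alternatives covered DESeq2 and its size factors, no filter on low counts, other sets of libraries in the fit, a block on the replicate number, leaving out each library, TPM, leaving out abundant genes, other windows, and those chosen later that are named with their values. The comparisons of 2 groups, the F test over stages and the interaction were run on simulated counts with 200 changed genes and the spread of the real data, and the scan with 2 seeded stretches. The set higher in meiocytes than in all 4 tissues, camera and the permutation tests of shares were not run on simulated data.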

Results

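RNA was measured by short-read sequencing of 45 libraries of hexaploid bread wheat, whose genome is made of the A, B and D subgenomes, so that most genes have homoeologous copies on related chromosomes. The libraries fell into 15 groups with 3 libraries each. The cultivar Chinese Spring was sampled as isolated meiocytes, the cells that go through meiosis, in 7 groups: pre-meiotic G2, leptotene, zygotene, pachytene, diplotene/diakinesis, metaphase I and metaphase II. Leaf, flag leaf, anther and pollen were sampled in Chinese Spring and in the line named CSPh1b, written ph1b here. The ph1b line is a mutant of Chinese Spring that lacks a part of chromosome 5B carrying the Ph1 locus, which restricts chromosome pairing in meiosis to true homologues. The 21 meiocyte libraries held 1250555 to 4955602 estimated counts each and the 24 libraries of other tissues 5478854 to 26844831. The 314690 genes comprised 107892 high-confidence and 161536 low-confidence reference genes and 45262 loci whose identifiers begin with MSTRG, the prefix that transcript assemblers give to loci found in the reads (assembled loci below). Values are means ± SD over 3 libraries unless another number is given. Nothing in the labels says that the 3 libraries of a group came from separate plants, so p-values measure only the spread between these samples.

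Meiocyte libraries detected fewer genes than leaf or anther libraries, and differed more from each other. After each library was thinned to 1250545 counts, the total of the smallest one, 24479 ± 6535 genes had a count in pre-meiotic G2, 26899 ± 13302 in leptotene, 40127 ± 17222 in zygotene, 48605 ± 16782 in pachytene, 34610 ± 16383 in diplotene/diakinesis, 43670 ± 4646 in metaphase I and 26781 ± 803 in metaphase II. Leaf of Chinese Spring had 66172 ± 296 detected genes, anther 66719 ± 1362, flag leaf 53638 ± 1207 and pollen 48215 ± 7111. Pearson's r between libraries of one stage, across genes on log2 CPM, lay between 0.528 in leptotene and 0.913 in pachytene. In the tissues of Chinese Spring it was 0.986 to 0.989 in leaf and 0.971 to 0.981 in flag leaf. It was 0.945 to 0.977 in anther and 0.913 to 0.954 in pollen, which met the top of the meiocyte range. Genes are not independent replicates, and these r describe the libraries only. The fewest genes were found in leptotene 1 (13740), diplotene/diakinesis 1 (15703), pre-meiotic G2 3 (17054) and zygotene 1 (20364). The depth and spread of the meiocyte libraries limit every comparison between stages.

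**Figure D1:**
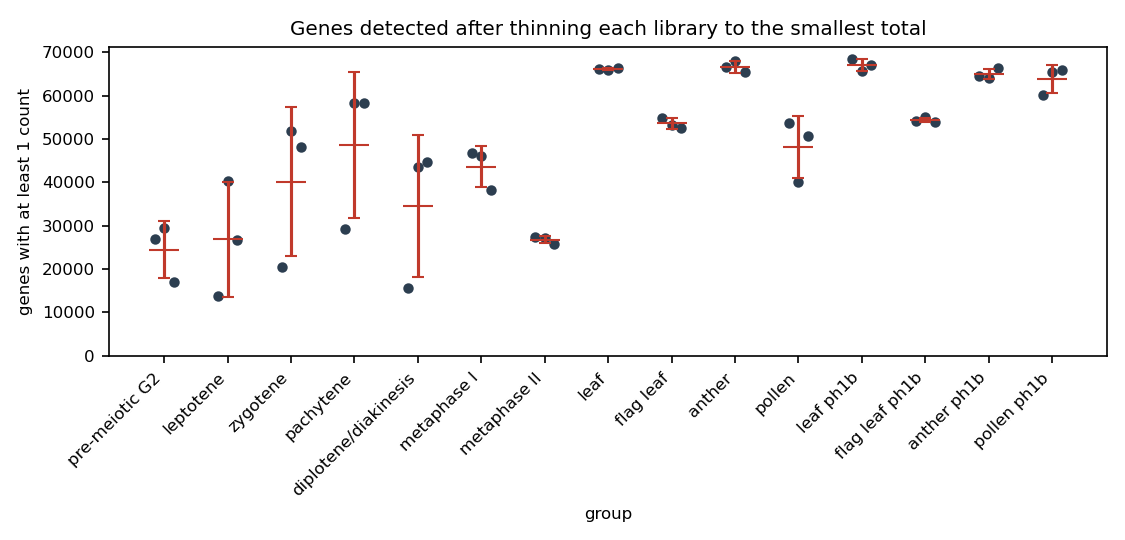
Number of genes with at least 1 count (y axis) in each library after thinning to the smallest total, by group (x axis); points are libraries, bars the mean and SD of 3. Meiocyte libraries ranged from 13740 to 58335 genes, and the Chinese Spring leaf and anther libraries from 65426 to 68141.

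The course of expression through meiosis was compared between consecutive stages and between its first and last stage. Across the 7 stages, 561 of 49569 tested genes changed by the F test of edgeR's quasi-likelihood method at a Benjamini-Hochberg adjusted p of 0.05. On simulated counts this test called 61 genes, 55 of them changed ones. Unchanged genes thus made up 9.84% of the calls, above the 5% aimed at, though 61 calls are too few to fix this share. It recovered 6% of 4-fold and 49% of 16-fold changes. The 561 comprised 311 high-confidence genes, 58 low-confidence genes and 192 assembled loci. From pre-meiotic G2 to metaphase II, 147 genes rose and 59 fell, and 128 of those that rose were high-confidence genes. The excess of rises shrank to 68 against 60 without pre-meiotic G2 1, and DESeq2 called 1444 and 949. On simulated counts this comparison of the first and last stage recovered 0% of 4-fold and 0% of 16-fold changes. The assembled locus MSTRG.152116 rose from 0 counts in the 3 pre-meiotic G2 libraries to 492 ± 87.3 CPM in metaphase II, at least 1150-fold when set against a floor of 3 counts over the group (edgeR adjusted p = 5.15e-24). TraesCS4B02G028500LC rose to 298 ± 104 CPM, at least 698-fold (edgeR adjusted p = 3.44e-08), while TraesCS2D02G325300 fell from 99.3 ± 59.8 CPM to 0 counts, at least 266-fold (edgeR adjusted p = 4.65e-05), and TraesCS3A02G264700 fell from 60.9 ± 27.4 CPM to 0, at least 163-fold (edgeR adjusted p = 0.000335).

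Between consecutive stages few genes passed the test. From pre-meiotic G2 to leptotene, 42 genes rose, among them TraesCS1D02G438400 (0 to 71.3 ± 27.9 CPM) and TraesCS4B02G191200 (0 to 54.5 ± 20.7 CPM). Another 9 fell, among them TraesCS1B02G136100LC (557 ± 499 to 32.2 ± 33.3 CPM) and MSTRG.155147 (8056 ± 1929 to 4903 ± 2854 CPM); MSTRG.155147 was not called by DESeq2 (adjusted p = 0.595), and its direction turned to a log2 fold of 0.134 without the 4 libraries with the fewest genes. Without leptotene 2, 39 genes rose and 59 fell. From leptotene to zygotene, 12 genes rose and 16 fell. The balance turned with DESeq2 (508 and 72), without the 4 libraries with the fewest genes (53 and 11) and without leptotene 2 (89 and 6). It turned in smaller ways with DESeq2's size factors (20 and 18) and without diplotene/diakinesis 1, pre-meiotic G2 3 or zygotene 1. TraesCS5B02G530400LC rose from 0 to 91.7 ± 30.7 CPM and TraesCSU02G570700LC from 0 to 29.1 ± 23.8 CPM, and the assembled loci MSTRG.11958 (968 ± 921 to 243 ± 36.9 CPM) and MSTRG.154720 (16600 ± 5784 to 8007 ± 741 CPM) fell. From zygotene to pachytene, 5 genes rose and 4 fell (51 and 20 with DESeq2, 7 and 14 without zygotene 1), and none met the rule for naming. From pachytene to diplotene/diakinesis, 29 rose and 11 fell, against 73 and 213 with DESeq2. Among those that fell were TraesCS6D02G105800 (99.0 ± 51.1 CPM to 0) and MSTRG.53012 (65.1 ± 17.3 CPM to 0). TraesCS3B02G260000LC and TraesCS5D02G457400 both rose from 0 to 25.1 ± 17.3 CPM with 269 counts each in the same libraries. They may share their reads, which was not tested, so the change of either is uncertain.

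From diplotene/diakinesis to metaphase I, 11 genes rose and 12 fell. The balance was not kept: 135 rose and 93 fell with DESeq2, 4 and 19 without the 4 libraries with the fewest genes, 2 and 14 without the first metaphase I library and 18 and 9 without the third. The assembled loci MSTRG.38497 (2.33 ± 2.07 to 138 ± 15.5 CPM) and MSTRG.51243 (103 ± 61.6 to 725 ± 910 CPM) rose, and MSTRG.95203 (53.4 ± 90.6 CPM to 0) and MSTRG.106369 (1348 ± 1287 to 222 ± 17.9 CPM) fell. DESeq2 called neither MSTRG.51243 (DESeq2 adjusted p = 1) nor MSTRG.106369 (DESeq2 adjusted p = 0.205). From metaphase I to metaphase II, TraesCS1D02G158000 was the gene that rose (0.227 ± 0.394 to 16.8 ± 10.7 CPM) and 61 genes fell, among them MSTRG.17098 (64.3 ± 64.6 CPM to 0) and TraesCS2B02G327300 (63.8 ± 11.2 CPM to 0). With size factors of DESeq2 in place of TMM scaling, 10 genes rose and 63 fell from metaphase I to metaphase II, and 5 rose and 10 fell from zygotene to pachytene. These counts were small next to the spread: the common dispersion was 2.79, and on simulated counts with the same spread the consecutive comparisons recovered 0% of genes changed 4-fold and 0 to 13.4% of those changed 16-fold. When only the 6 libraries of the stages compared were fitted, edgeR called at most 16 genes between consecutive stages and 41 between pre-meiotic G2 and metaphase II. In these fits TraesCS1B02G136100LC and TraesCS2B02G327300 were the only genes named between consecutive stages that were still called, and TraesCS3A02G264700 was not called between the first and last stage. DESeq2, fitted on all 21 meiocyte libraries with 49569 tested genes, called 71 to 1226 genes between consecutive stages and 2393 between the first and last.

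Meiocytes as a whole were compared with each of the 4 other tissues to find what sets meiotic cells apart. Assembled loci took 17.2 ± 4.26% of the counts in meiocytes (n = 21), against 1.5 ± 0.006% in leaf, 5.22 ± 3.20% in flag leaf, 2.48 ± 0.272% in anther and 6.31 ± 0.326% in pollen of Chinese Spring. High-confidence genes took 73.1 ± 6.65% of counts in meiocytes (n = 21), against 94.8 ± 0.030%, 89.9 ± 4.02%, 92.9 ± 0.481% and 88.1 ± 0.700% in the same tissues. Low-confidence genes took 9.64 ± 2.81% in meiocytes (n = 21) and 3.74 to 5.56% in the tissues. In TPM, which divides by length, assembled loci took 29.7 to 40.4% in the 7 meiocyte groups, against 3.31, 13.3, 6.05 and 12.6% in leaf, flag leaf, anther and pollen, and high-confidence genes 38.9 to 50.3% against 89.1, 77.3, 84.5 and 76.8%. In each of the 12 comparisons of count shares every meiocyte library lay outside the range of the tissue (exact permutation test, two-sided, p = 0.000988, the smallest that 21 against 3 libraries can give; adjusted p = 0.00241 over 39 tests of shares). The share of assembled loci was 20.1 ± 7.21% in pre-meiotic G2, 21.2 ± 6.96% in leptotene, 15.6 ± 0.863% in zygotene, 14.7 ± 1.87% in pachytene, 17.4 ± 1.49% in diplotene/diakinesis, 16.0 ± 4.35% in metaphase I and 15.6 ± 0.646% in metaphase II. Which reads these loci were assembled from is not given. If meiocyte reads were among them, a higher share in meiocytes would be in part built in.

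**Figure D2:**
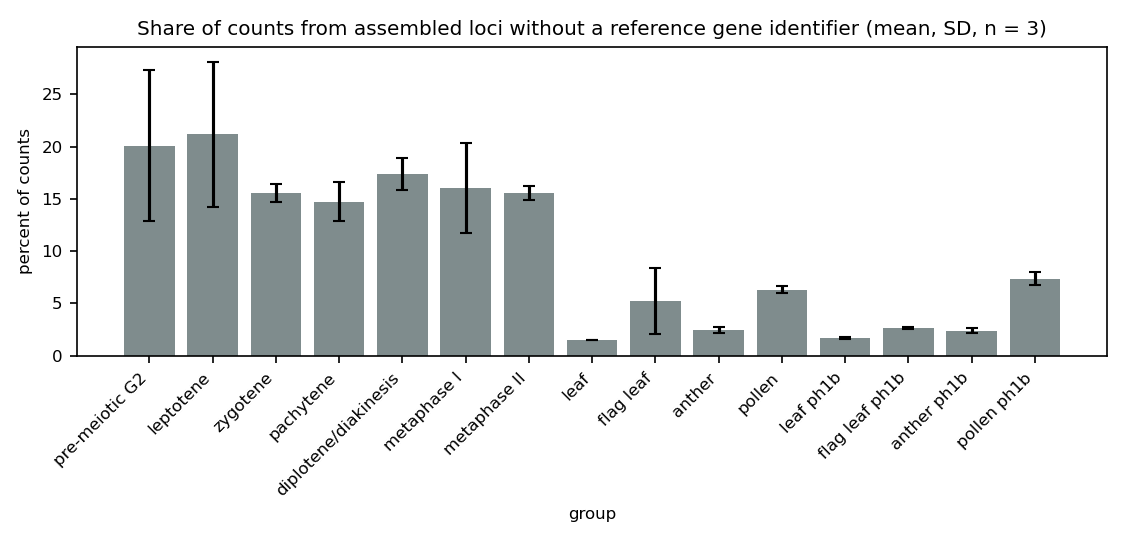
Percent of all counts (y axis) that came from assembled loci without a reference gene identifier, by group (x axis); bars are means and whiskers SD of 3 libraries. The 7 meiocyte groups had means of 14.7 to 21.2%, and the other tissues 1.5 to 7.35%.

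Single genes differed between meiocytes and tissues by large factors. In leaf, TraesCS1D02G061800 had no count in 3 libraries and 476 ± 195 CPM in meiocytes (n = 21), at least 10900-fold higher, and TraesCS2A02G593100 had 1033 ± 1222 CPM in meiocytes (n = 21) against 0, at least 23600-fold. TraesCS2B02G079200 had 1829 ± 86.3 CPM in leaf and 2799 ± 145 CPM in flag leaf and no count in any of the 21 meiocyte libraries, at least 40400-fold and 61800-fold lower. TraesCS2D02G065200 had 1828 ± 185 CPM in leaf, 3078 ± 86.7 CPM in flag leaf and 0.150 ± 0.688 CPM in meiocytes (n = 21). Against flag leaf, TraesCS5D02G359600 (215 ± 127 CPM, n = 21, against 0; at least 1210-fold) and TraesCS1A02G132400 (138 ± 55.2 CPM, n = 21, against 0; at least 774-fold) were higher in meiocytes. Against anther, TraesCSU02G321700LC (46.4 ± 38.0 against 0.101 ± 0.176 CPM) and TraesCS5B02G152200LC (267 ± 180 against 0.601 ± 0.550 CPM) were higher, and TraesCSU02G262700 (1.63 ± 7.47 against 118 ± 4.79 CPM) and TraesCS3D02G255300 (0 against 29.4 ± 44.9 CPM) lower. Against pollen, TraesCS1B02G017700 (152 ± 104 CPM against 0; at least 1670-fold) and TraesCS7A02G557400 (163 ± 108 CPM against 0; at least 1790-fold) were higher, and TraesCS3A02G326400 (0 against 4077 ± 303 CPM; at least 90100-fold) and TraesCS3B02G423500 (0 against 3034 ± 1367 CPM; at least 67000-fold) lower. Adjusted p-values of these 14 genes by edgeR's quasi-likelihood test lay between 3.02e-13 and 0.000576, and every one kept its direction and its side of the threshold under each alternative run.

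The number of genes that differ was far less certain. Fitted with the mean of the 7 stage coefficients as fixed in advance, 1670 genes were higher and 26937 lower in meiocytes than in leaf, 2021 and 22407 than in flag leaf, 626 and 21110 than in anther, and 2890 and 24491 than in pollen, of 69319 tested. On simulated counts this contrast was faulty. Unchanged genes made up 50.5% of calls against leaf, 26.0% against flag leaf, 57.1% against anther and 41.7% against pollen. Every one of these unchanged genes was called lower. With 200 changed genes in the simulation, they numbered 51, 13, 48 and 25. The shares show a bias towards lower calls and do not give the false share of the real calls. Of the genes called lower against leaf in the real data, 87.4% had a stage with 0 counts in all 3 libraries, against 63.5% of all tested genes. Genes truly lower in meiocytes would also have such stages more often, so this does not tell false calls apart. With the 21 meiocyte libraries as one group, a contrast chosen after the simulation, unchanged genes made up 4.55, 6.06, 0 and 3.70% of simulated calls. Those shares rest on 2, 2, 0 and 1 unchanged genes. The simulation gave each unchanged gene the same mean and spread in all libraries, and each changed gene the same fold in all stages. Pooling the stages suits such counts by construction, so the shares do not vouch for the real calls. With one group the real calls were 1816 higher and 13349 lower against leaf and 1973 and 11518 against flag leaf. They were 403 and 2585 against anther and 2967 and 14048 against pollen. Of them, 14882, 13381, 2981 and 16830 were also called by the first contrast. In simulation the one-group contrast recovered only 0 to 4.48% of 4-fold and 37.3 to 56.7% of 16-fold changes. The first contrast recovered 4.48 to 7.46% and 47.8 to 65.7%, and how many of its real calls are false is not known. The median log2 difference over all tested genes was -1.57, -1.10, -1.53 and -1.19 in the first contrast and -0.58, -0.18, -0.56 and -0.13 in the other, and -1.79, -1.48, -1.51 and -2.04 in the first contrast with DESeq2's size factors, so a fold has to be read against that shift.

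Genes higher in meiocytes than in all 4 tissues were counted as the set most specific to meiotic cells. There were 103 of them by the first contrast and 71 with meiocytes as one group, 70 of which were shared. Of the 103, 50 were assembled loci, 44 high-confidence and 9 low-confidence genes. Assembled loci were over-represented among them (48.5% of the set against 11.1% of tested genes; odds ratio 7.59, 95% interval 5.05 to 11.4, Fisher's exact test). Of the 71, they made up 42 (59.2%; odds ratio 11.7, 95% interval 7.08 to 19.4, Fisher's exact test), with 22 high-confidence and 7 low-confidence genes. By the first contrast the number was 49 with DESeq2's size factors and 164 with all libraries thinned to the smallest total. It was 311 without the 4 libraries with the fewest genes. Leaving out 1 library gave 40 (without pollen 3) to 130. The excess of assembled loci is descriptive, since loci assembled from meiocyte reads would favour meiocytes, and the reads used are not given.

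Counts of placed reference genes were split about evenly between the subgenomes. In meiocytes the A, B and D subgenomes took 32.7 ± 0.317%, 33.8 ± 0.340% and 33.5 ± 0.342% (n = 21), against 33.2 ± 0.090%, 32.8 ± 0.219% and 34.1 ± 0.129% in leaf. The B share in meiocytes was 1.00 percentage point above leaf and 1.11 above flag leaf (exact permutation test, adjusted p = 0.00241 for both), and the D share was 0.770 above pollen (exact permutation test, adjusted p = 0.00241). The A share differed from pollen by -0.878 percentage points (exact permutation test, adjusted p = 0.00241). These differences depended on abundant genes and on the scale. Without the 100 most abundant genes of each library they were -0.213, -0.332, -0.019 and 0.549 percentage points. The last, A against pollen, then passed in the opposite direction (exact permutation test, adjusted p = 0.04 over 27 tests). B differed from pollen by -0.531 (exact permutation test, adjusted p = 0.04). With TPM the B differences from leaf and flag leaf were 1.641 and 2.843 (exact permutation test, adjusted p = 0.00667 for both). Those from pollen were -0.093 for D and 0.323 for A. From pre-meiotic G2 to metaphase II the shares of counts moved by at most 0.326 percentage points (exact permutation test, adjusted p = 0.260 to 0.949; 3 against 3 libraries cannot give a p under 0.1). With TPM they moved by -2.008 for B, without overlap between the libraries (exact permutation test, p = 0.1), by 1.131 for D and by 0.877 for A, so that a change of the shares through meiosis stays undecided.

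Flag leaf and leaf, both vegetative, differed less than pollen and anther. In flag leaf, 111 genes were higher and 126 lower than in leaf. The balance changed to 391 and 782 with DESeq2, 304 and 797 without the 4 meiocyte libraries with the fewest genes, 23 and 101 without flag leaf 1, 139 and 43 without flag leaf 2 and 101 and 41 without flag leaf 3. The rule for naming gave TraesCS2D02G016100 (75.7 ± 26.0 CPM against 0) and TraesCS2B02G200800 (65 ± 14.2 CPM against 0), and TraesCS2B02G289900 (0 against 136 ± 30.0 CPM) and TraesCSU02G137400 (0 against 115 ± 64.3 CPM). DESeq2 called neither TraesCS2D02G016100 (DESeq2 adjusted p = 0.769) nor TraesCSU02G137400 (DESeq2 adjusted p = 1), and both calls ended when any 1 leaf or flag leaf library was left out. In pollen, 5354 genes were higher and 2098 lower than in anther. TraesCS6D02G025300 had 3034 ± 346 CPM in pollen and no count in anther, at least 52100-fold higher, and TraesCS4B02G327700 had 1096 ± 148 CPM against 0, at least 18800-fold. TraesCS6A02G027000 had no count in pollen and 499 ± 747 CPM in anther, and TraesCSU02G125300 none in pollen and 326 ± 148 CPM in anther. These 2 comparisons took their dispersion from a fit with the 21 meiocyte libraries (common dispersion 1.48). On simulated counts they found 0% and 1.49% of 16-fold changes. The simulated tissue libraries were drawn with the spread of that fit too, so these shares do not measure recovery in the real ones. Fitted on the libraries compared alone, 28254 and 36072 genes were called. Pollen then had 15226 genes higher and 20846 lower than anther, so the balance of that comparison turned with the fit. With DESeq2's size factors, 7122 genes were higher and 1202 lower in pollen, and the median log2 difference of all genes moved from -0.27 to 0.43.

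The ph1b line was compared with Chinese Spring in leaf, flag leaf, anther and pollen. The gene fixed in advance as a marker of the deleted part of 5B, TraesCS5B02G255100, checked the labels. It had 3.75 ± 0.052 CPM in leaf, 4.04 ± 0.580 in flag leaf, 16.6 ± 0.40 in anther and 3.47 ± 1.94 in pollen of Chinese Spring, and in the 12 ph1b libraries it had 1 count in all, in anther. That is at least 76.4-fold lower in leaf, 26.2-fold in flag leaf and 41.3-fold in pollen (edgeR adjusted p = 0.00196, 0.00184 and 0.00822), and it was lower in anther too (edgeR adjusted p = 0.0019).

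The loss covered a continuous stretch of chromosome 5B from TraesCS5B02G220600 to TraesCS5B02G268600, which holds 470 annotated high-confidence genes, 253 of them expressed. Their summed expression fell from 3665 ± 108 to 22.7 ± 3.81 CPM in leaf, from 2812 ± 47.1 to 22.6 ± 2.45 in flag leaf, from 3140 ± 134 to 22.2 ± 1.88 in anther and from 1867 ± 161 to 14.4 ± 5.06 in pollen. The same ends of the stretch were found with windows of 15, 25 and 51 genes and with TPM. Among the 5 genes lost from 5B with the highest expression in Chinese Spring, TraesCS5B02G258900 had 525 ± 78.5 CPM in anther of Chinese Spring and 6.06 ± 2.57 in ph1b, TraesCS5B02G413000LC 316 ± 22.3 and 3.06 ± 0.329, and TraesCS5B02G238400 210 ± 66.6 and 0.620 ± 0.051. In pollen, TraesCS5B02G227200 had 408 ± 45.3 and 0.736 ± 0.372 CPM, and TraesCS5B02G262900 365 ± 98.6 and 0.379 ± 0.338. All 5 passed the test in each tissue, with edgeR adjusted p of 2.26e-06 to 0.0164. The call of TraesCS5B02G258900 in pollen ended without Chinese Spring 3 or ph1b 2, that of TraesCS5B02G262900 in anther without Chinese Spring 1 or 2 or any ph1b library, and that of TraesCS5B02G227200 in anther without Chinese Spring 1 or ph1b 2.

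**Figure D3:**
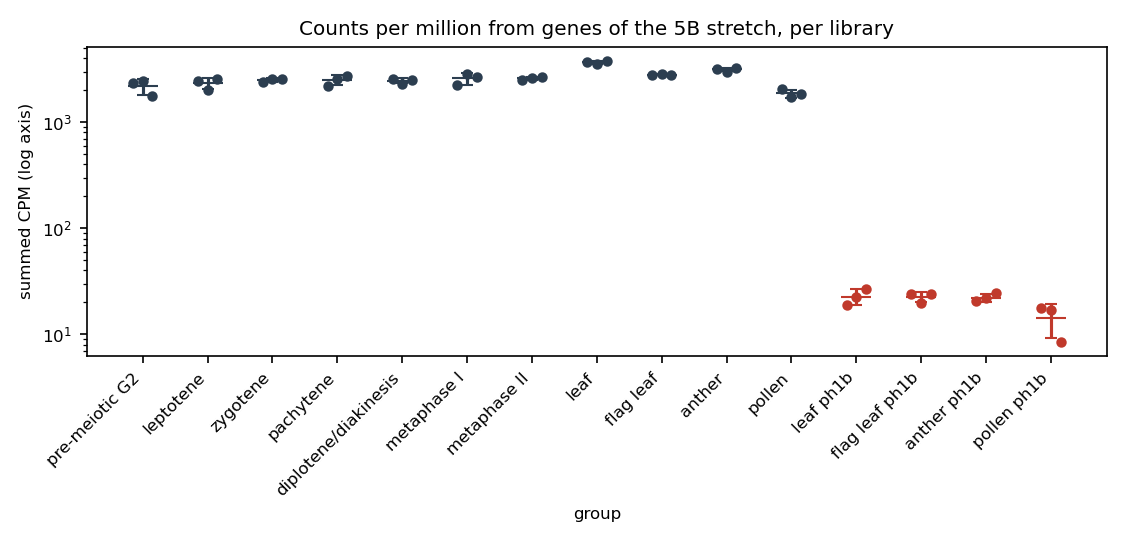
Summed CPM (y axis, log scale) of the 470 high-confidence genes between the ends of the 5B stretch, by group (x axis); points are libraries, bars the mean and SD of 3. Group means in Chinese Spring lay between 1867 and 3665 CPM and in ph1b between 14.4 and 22.7 CPM.

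Other stretches were lower (called lost) or higher (called gained) in ph1b than in Chinese Spring as well. The scan over the median of the 4 tissues found 19 stretches of at least 15 high-confidence genes, 4 lost (on 2A, 3B, 5B and 7A) and 15 gained. On 3B, 47 expressed genes from TraesCS3B02G310300 to TraesCS3B02G316900 fell, from 448 ± 11.9 to 2.45 ± 1.06 CPM in leaf, 299 ± 36.5 to 2.89 ± 0.588 in flag leaf, 401 ± 25.5 to 1.35 ± 0.657 in anther and 1049 ± 28.2 to 123 ± 66.2 in pollen. On 7B, 38 genes from TraesCS7B02G209900 to TraesCS7B02G216000 were higher in ph1b. They went from 2.49 ± 0.534 to 355 ± 143 CPM in leaf, 1.91 ± 1.01 to 317 ± 125 in flag leaf, 4.89 ± 0.648 to 738 ± 263 in anther and 1.78 ± 1.02 to 742 ± 116 in pollen. Their median log2 of 7.873 was close in size to those of the lost stretches on 5B (-8.279) and 3B (-8.099). The other gained high-confidence stretches had medians of 0.447 to 0.806. As Chinese Spring was near 0 in the 7B stretch, a gain in ph1b cannot be told apart there from a lack or silence in the sampled Chinese Spring. The number of stretches was 24 with a window of 15 genes, 11 with 51 and 35 with TPM. On simulated data the scan recovered 2 of 2 seeded stretches and called no other. Those were shifted further than most gained stretches, in values shuffled over genes with a reduced spread. The simulation therefore gives little assurance for the gained stretches.

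Some stretches differed between libraries of ph1b. On 7A, 196 genes from TraesCS7A02G514200 to TraesCS7A02G566500 were lost in leaf (2448 ± 42.2 to 15.2 ± 3.01 CPM) and flag leaf (1849 ± 66.9 to 26.9 ± 7.81 CPM), with library medians of -3.26 to -3.77 on the log2 scale. In anther the medians were -3.53 and -3.56 in ph1b 1 and 2 and 0.61 in ph1b 3, and in pollen 0.38, 0.98 and 0.63. At the end of 7D, from TraesCS7D02G497700 to TraesCS7D02G552600, the medians were 0.85 to 1.01 in the 6 leaf and flag leaf libraries, 0.88, 0.96 and -0.79 in anther and -1.07, -1.07 and -1.06 in pollen. At the end of 2A, from TraesCS2A02G558100 to TraesCS2A02G577000, they were -3.84, -2.83 and -0.56 in leaf, -3.07, 0.05 and 0.06 in flag leaf, 0.11, -3.32 and -0.91 in anther and -1.06, -1.36 and -1.08 in pollen.

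Whole chromosomes also moved in single libraries. The median log2 ratio of chromosome 7B lay between -0.83 and -0.88 in leaf 1 and 3, flag leaf 2 and 3 and anther 1 and 2 of ph1b. Chromosome 2A had medians of -1.09, -1.49 and -1.17 in the 3 pollen libraries, -0.68 in anther 3 and 0.48 in leaf 3. In flag leaf 2 and 3, chromosome 3A had medians of 0.18 and 0.16 and 3D of -0.19 and -0.20. In Chinese Spring leaf, flag leaf and anther libraries, each set against the other 2, none of 1298 bins of 50 expressed genes was lost and 1 was raised, against 135 lost and 276 raised bin values in the 9 ph1b libraries, 5B and 3B included.

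**Figure D4:**
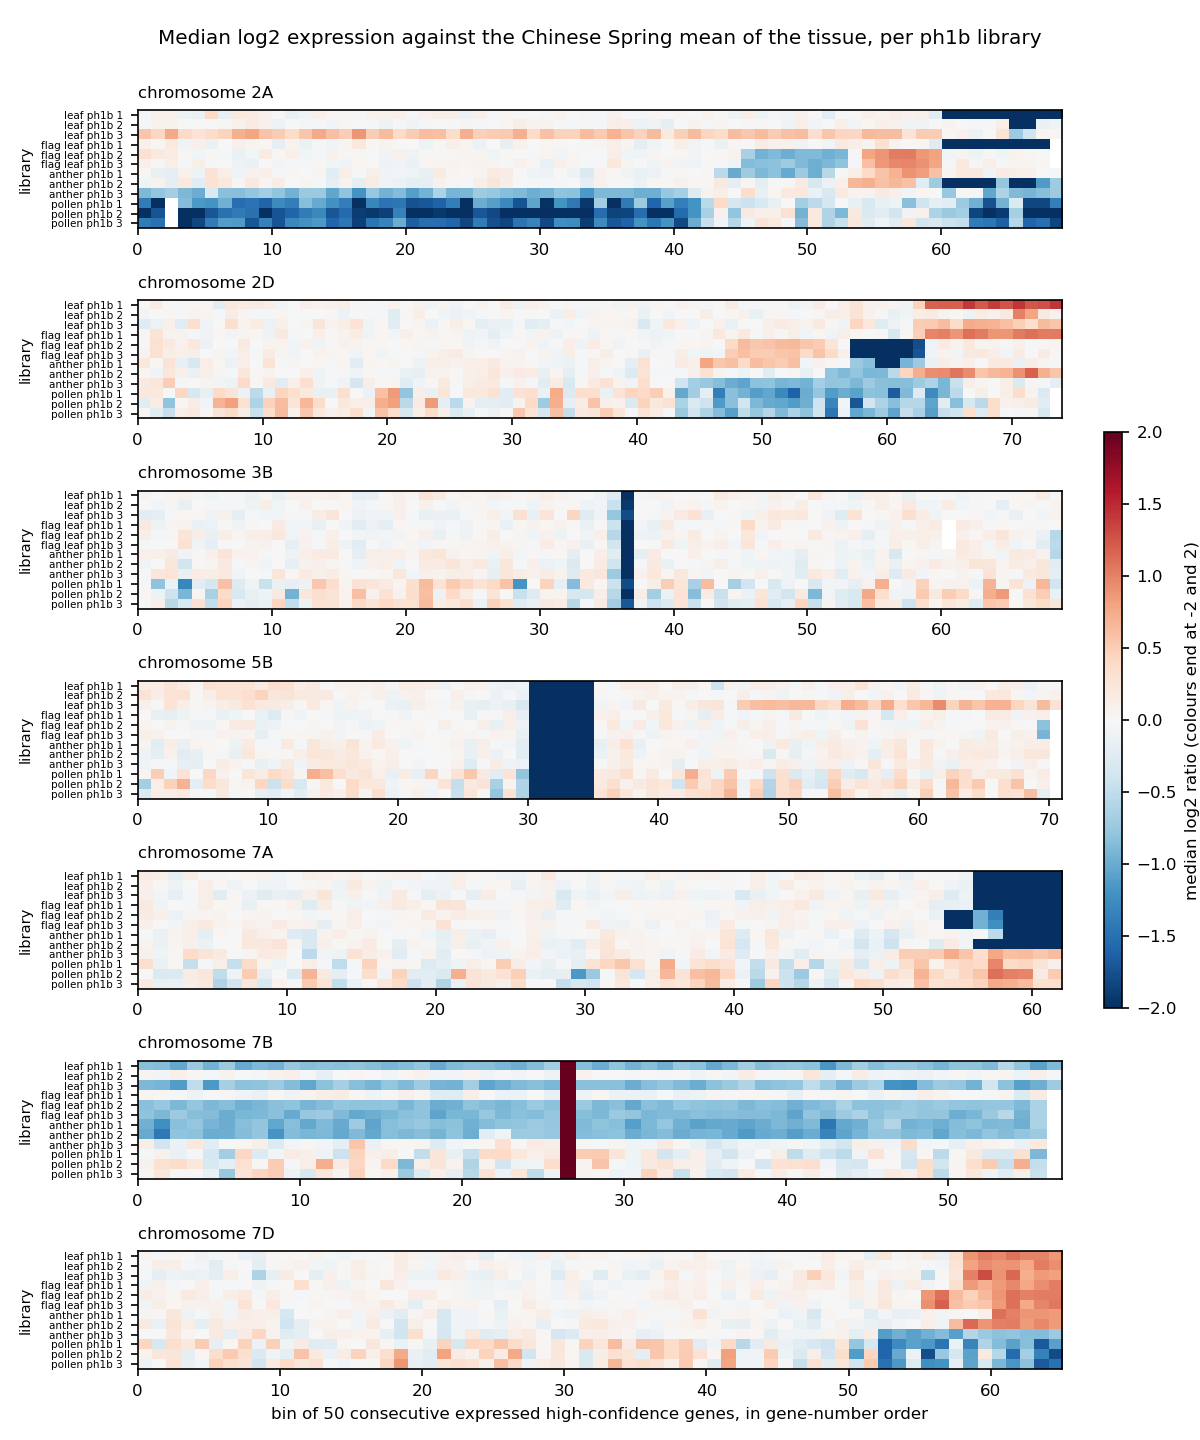
Median log2 expression against the Chinese Spring mean of the same tissue (colour; the scale ends at -2 and 2, white is near 0 or no value) in bins of 50 expressed high-confidence genes along 7 chromosomes (x axis) for each of the 12 ph1b libraries (y axis). The lost part of 5B runs through every library, while the blocks on 2A, 2D, 7A, 7B and 7D differ between libraries.

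Genes that differed between ph1b and Chinese Spring were counted in each tissue and set against these stretches. In leaf, 187 genes were higher and 698 lower in ph1b, 254 of the latter on 5B, of 68128 tested; DESeq2 called 1161 higher and 1145 lower. Flag leaf had 154 higher and 324 lower (131 on 5B, of 37873 tested), anther 112 and 347 (181 on 5B, of 61046) and pollen 4288 and 5789 (309 on 5B, of 50250). Of placed high-confidence genes called, 75.4% in leaf lay in bins lost or raised in a library of that tissue, which held 7.56% of the tested genes. The shares were 71.2% against 6.0% in flag leaf, 58.4% against 4.68% in anther and 20.3% against 17.7% in pollen. The bins were chosen by the ratios of the same libraries and genes, which in part fixes such an excess, so these shares are descriptive. Outside such bins 164 genes were called in leaf, 111 in flag leaf, 136 in anther and 6065 in pollen.

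Several of the genes called with the largest changes lay in these stretches. In leaf, flag leaf and anther TraesCS7B02G385600LC rose from 0 to 36.0 ± 11.8, 22.0 ± 3.91 and 33.1 ± 9.78 CPM, and TraesCS7B02G385700LC from 0 to 16.8 ± 6.34 CPM in leaf and 17.8 ± 5.45 in anther; TraesCS7B02G214900 rose from 0 to 17.1 ± 8.19 CPM in flag leaf. The 3B genes TraesCS3B02G311400 (leaf, 83.2 ± 3.85 CPM), TraesCS3B02G314300 (flag leaf, 89.8 ± 37.4 CPM) and TraesCS3B02G313000 (anther, 74.7 ± 8.94 CPM) fell to 0 counts, at least 1700-fold, 582-fold and 1020-fold. The 5B genes TraesCS5B02G416400LC (leaf, anther and pollen), TraesCS5B02G242000 (flag leaf) and TraesCS5B02G243600 (pollen, 55.3 ± 5.11 CPM) fell to 0 counts as well. The call of TraesCS7B02G385700LC in anther ended without ph1b 2, and that of TraesCS5B02G416400LC in anther without Chinese Spring 1 or any ph1b library. In pollen MSTRG.140026 rose from 0 to 69.8 ± 4.74 CPM and TraesCS5A02G092900 from 0 to 28.7 ± 13.0 CPM (edgeR adjusted p = 0.00216 and 0.00461). Neither was in a stretch found by the scan. The same holds for TraesCS7B02G385600LC and TraesCS7B02G385700LC, which belong to the separate low-confidence series.

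These counts moved with single libraries and settings. In anther 459 genes were called, 103 to 135 without anther Chinese Spring 1 or 2 or ph1b 1 or 2 and 6923 without Chinese Spring 3, 1928 with all 24 libraries in one fit and 3421 with DESeq2. Pollen had 10077, 6816 higher and 6302 lower without ph1b 1, 1777 in all without ph1b 2, 3535 without Chinese Spring 2 and 26528 with all 24 libraries in one fit; flag leaf had 478, 1688 without ph1b 1 and 301 with all 24 libraries in one fit, and leaf 885, 453 to 495 without any of the Chinese Spring libraries. On simulated counts the test recovered 82.1% of 4-fold changes in leaf, 95.5% in flag leaf, 58.2% in anther and 11.9% in pollen, with unchanged genes making up 2.74 to 4.82% of calls.

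Whether the effect of ph1b differed between tissues was tested with an interaction term over all 24 libraries. It differed for 10387 of 87821 genes (edgeR quasi-likelihood F test), 9101 of them high-confidence genes and 481 on 5B. The ph1b libraries of the tissues also differed in stretches and whole chromosomes. Chromosome 2A was lower in the pollen libraries (medians -1.09, -1.49 and -1.17), and the 7A stretch was lost in leaf and flag leaf but not in pollen. The interaction cannot tell such differences between the sampled material from an effect of ph1b that depends on the tissue. On simulated counts unchanged genes made up 6.02% of the calls of this test. DESeq2 called 18542, and leaving out single libraries gave 7455 to 12436.

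The share of counts per subgenome moved in ph1b by up to 1.60 percentage points. In pollen the A share was 32.0 ± 0.090% in ph1b and 33.6 ± 0.058% in Chinese Spring, and the B share 35.0 ± 0.131% and 33.7 ± 0.060%. Without the 100 most abundant genes of each library the pollen differences shrank from -1.602 to -0.597 percentage points for A and from 1.305 to 0.760 for B. In leaf the B share was 31.6 ± 0.945% and 32.8 ± 0.219% and the D share 35.1 ± 1.01% and 34.1 ± 0.129%. In flag leaf the B share was 31.8 ± 0.618% and 32.7 ± 0.085%. In anther the differences were -1.03 percentage points for B and 1.026 for D, with overlap between the libraries. None passed the adjustment (exact permutation test, adjusted p = 0.144 or more), since 3 against 3 libraries cannot give a p under 0.1.

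Classes of genes, subgenomes and chromosomes were tested as sets with limma's camera at a preset correlation of 0.01. Of 459 tests over 17 comparisons, 16 passed. Against the other genes, assembled loci were higher in meiocytes than in leaf, flag leaf and anther, in flag leaf than in leaf and in pollen than in anther, and high-confidence genes were lower in meiocytes than in leaf and anther and in pollen than in anther. In ph1b, genes of 7B were lower in leaf, flag leaf and anther, 7A lower in leaf, 3A and 7D higher and 3D lower in flag leaf, and 2A lower in pollen. With a correlation estimated from the data 0 of the 459 tests passed, and the adjusted p of these 16 were then 0.241 to 1 (limma camera).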

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

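The planned test of the interaction marked 1 result, because the difference between ph1b and Chinese Spring varied over leaf, flag leaf, anther and pollen for 10387 genes (edgeR quasi-likelihood F test over 24 libraries). Stretches and whole chromosomes also differed between the ph1b libraries of these tissues. An effect that depends on the tissue cannot be told apart from such differences. Genotype labels were shuffled within each tissue in 24 other splits of the libraries, and 1 of 25 splits, the real one, gave as many genes. Shuffling also removes a genotype effect common to the tissues, so the splits cannot show that the effect differs between them. A share of 1 in 25 is the smallest they can give, and the highest of the other splits gave 9773, the rest at most 153. What set that split apart was not examined. Most genes called in a single tissue were in pollen (10077, against 885, 478 and 459 in leaf, flag leaf and anther), and explanations for pollen are weighed under the other observations.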

How the results depend on the processing

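The alternatives were chosen before the data were examined, except these: thinning, leaving out the 4 meiocyte libraries with the fewest genes, meiocytes as one group, and counting outside lost or raised bins. Of 2045 values of 62 named genes under alternatives, 1880 kept their direction and side of the threshold, 164 kept the direction only and 1 reversed, MSTRG.155147 (log2 0.134 without the 4 libraries). The fixed gene TraesCS5B02G255100 and the ends of the 5B stretch held under every alternative run. For the changes below the cause was not tested, except that fewer libraries or genes tested, or a changed spread, follow from how an alternative was made. Low depth of the meiocyte libraries is one limit of the stage comparisons.

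With DESeq2, 984 genes changed across stages, and consecutive stages gave 1226, 580, 71, 286, 228 and 899 in order. Metaphase II against pre-meiotic G2 gave 2393, meiocytes against anther 5856, flag leaf against leaf 1173, ph1b leaf 2306, ph1b anther 3421 and the interaction 18542. DESeq2's size factors gave 15 for pachytene against zygotene, 71 for diplotene/diakinesis against pachytene and 38 for metaphase I against diplotene/diakinesis. They gave 49 genes higher in meiocytes than in all 4 tissues. Fitting only the libraries compared gave 4, 0, 0, 7, 0 and 16 genes for consecutive stages in edgeR (unadjusted p under 0.05 in the joint fit: 3497, 747 and 2360 where it gave 0), and 41 for metaphase II against pre-meiotic G2. It gave 16487, 13386, 6109 and 16111 for meiocytes against leaf, flag leaf, anther and pollen, 28254 for flag leaf against leaf and 36072 for pollen against anther. Meiocytes as one group gave 15165, 13491, 2988 and 17015. Thinning gave 13618, 12713, 6680 and 13252, with 164 higher in meiocytes than in all 4 tissues. Without a low-count filter the counts were 55686, 37324, 39403 and 53769, with 42 higher in meiocytes than in all 4 tissues. No filter gave 1446, 3247 and 1892 for ph1b leaf, flag leaf and anther. Without the 4 libraries the counts were 1008 across stages, 205 for leptotene against pre-meiotic G2, 64 for zygotene against leptotene, 88 for diplotene/diakinesis against pachytene, 257 for metaphase II against metaphase I and 726 against pre-meiotic G2. They were 1101 for flag leaf against leaf, 13716 for pollen against anther and 311 higher in meiocytes than in all 4 tissues.

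For ph1b, all 24 libraries in one fit gave 301 in flag leaf, 1928 in anther and 26528 in pollen. Without the genes of the 5B stretch, leaf gave 524, flag leaf 316 and anther 120. Outside lost or raised bins the counts were 164, 111, 136 and 6065. A block on the replicate number gave 461 in leaf, 49 in anther, 1586 in pollen and 42 for metaphase I against diplotene/diakinesis. In the check for pairing, 0 of 13 comparisons had every same-number r over 0.1. The scan gave 11 stretches with a window of 51 genes and 35 with TPM, and camera with an estimated correlation 0 sets.

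Subgenome share differences, in percentage points, turned or lost their call as follows. With TPM, A was -0.003 against leaf, -0.512 against flag leaf, 0.164 against anther and 0.323 against pollen, B -0.230 against pollen, and D -0.610 against anther and -0.093 against pollen. Without the 100 most abundant genes, A was 0.302, -0.022, 0.183 and 0.549 against leaf, flag leaf, anther and pollen, B -0.213, -0.332, -0.187 and -0.531, and D -0.089 against leaf, 0.354 against flag leaf and -0.019 against pollen. It was then -0.044 for A in ph1b leaf, 0.460 for D in ph1b flag leaf, -0.164 for D in ph1b pollen, and -0.443 for A and 0.283 for B from pre-meiotic G2 to metaphase II.

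Leaving out 1 library at a time, the count across stages ranged from 348 to 7.0e+02 (348 without metaphase I 1, 371 without metaphase I 2). Leptotene against pre-meiotic G2 ranged from 37 to 98 (88 without leptotene 1, 98 without leptotene 2), zygotene against leptotene from 22 to 95 (95 without leptotene 2) and pachytene against zygotene from 6 to 21 (15 without leptotene 1, 21 without zygotene 1). Diplotene/diakinesis against pachytene ranged from 30 to 65 (65 without leptotene 1), metaphase I against diplotene/diakinesis from 16 to 33, metaphase II against metaphase I from 35 to 77 (35 without metaphase I 1) and against pre-meiotic G2 from 128 to 298 (128 without pre-meiotic G2 1). With the first contrast, the mean of the stage coefficients, meiocytes gave 26632 to 32911 against leaf and 21832 to 27390 against flag leaf. They gave 16286 to 26717 against anther and 24245 to 31328 against pollen. Flag leaf against leaf ranged from 66 to 364 (67, 91 and 66 without leaf 1, 2 and 3, 124 and 142 without flag leaf 1 and 3, 364 without leptotene 1), and pollen against anther from 4443 to 9300 (4443, 4645 and 4532 without anther 1, 2 and 3). The number higher in meiocytes than in all 4 tissues ranged from 40 to 130 (67 without anther 1, 50 and 51 without flag leaf 2 and 3, 46 and 40 without pollen 1 and 3).

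In ph1b leaf the range was 453 to 933 (495, 467 and 453 without Chinese Spring 1, 2 and 3) and in flag leaf 352 to 1688 (1688 without ph1b 1). In anther it was 103 to 6923 (103, 135 and 6923 without Chinese Spring 1, 2 and 3, 122 and 116 without ph1b 1 and 2), in pollen 1777 to 13118 (6580, 3535 and 3605 without Chinese Spring 1, 2 and 3, 1777 and 5730 without ph1b 2 and 3), and for the interaction 7455 to 12436. Share differences ranged from -0.544 to 0.467 for A in ph1b leaf, -0.297 to 0.131 for D in ph1b flag leaf and -0.136 to 0.166 for A in ph1b anther. Against leaf they were -0.471 to -0.388 for A and -0.610 to -0.491 for D, against flag leaf -0.732 to -0.523 for A and -0.632 to -0.350 for D, and against anther -0.664 to -0.433 for A and 0.235 to 0.412 for B. From pre-meiotic G2 to metaphase II they were -0.151 to 0.187 for A and -0.570 to 0.041 for B.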

Other observations

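Chosen after the result was seen were the tests of exchange, compensation and bin noise, of sequencing depth in meiocytes, and of anther RNA as the whole cause and of a different pollen stage; the other tests were set down before their results were seen. Low-confidence genes of 5B, from TraesCS5B02G360800LC to TraesCS5B02G437300LC, fell with the high-confidence stretch, from a summed 266 ± 39.0 to 7.04 ± 0.880 CPM in leaf and from 514 ± 61.7 to 10.3 ± 0.727 CPM in anther. In the 3B stretch, ph1b pollen had 123 ± 66.2 CPM with counts in 8 of 66 genes. The 7B stretch from TraesCS7B02G209900, higher in ph1b, had 0.128 to 4.49 CPM in the meiocyte stages of Chinese Spring, so it was low there too.

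Stretches on chromosomes other than 5B and 3B were lost or raised in single ph1b leaf, flag leaf and anther libraries. Noise of bins is argued against by 0 lost bins in 9 Chinese Spring libraries, against 83 outside the 5B and 3B stretches in 9 ph1b libraries, of which anther 3 had 0. Compensation by the remaining homoeologs, or reads moving to them, is argued against by a median log2 of 0.032 in the 5A and 5D bins across from the lost 5B stretch (quartiles -0.053 to 0.115). Of these 83, 73 (88.0%) had a raised bin at the same relative position of a homoeologous chromosome, against 10% at other chromosomes. Neighbouring bins of one stretch, and the same stretch lost in several libraries, were counted separately. The 83 are therefore not independent observations, and the percentages are descriptive. How many separate events they stand for was not counted, and the libraries may come from related plants. The pattern is consistent with exchange or copy change between homoeologous chromosomes that differs between the sampled plants, a hypothesis found and tested on the same data.

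Few genes were detected in meiocytes, with a large spread between libraries. Against leaf and anther, sequencing depth alone is argued against, as 0 of 21 libraries reached the lowest of theirs after thinning. Against flag leaf, only pachytene 2 and 3 (58252 and 58335 genes) reached its lowest library (52609), which argues against depth alone for the others. Against flag leaf and pollen together, 9 of 21 reached the lowest, Chinese Spring pollen 2 (40184), and the ratio of medians was 0.554. Against pollen depth therefore cannot be told apart. Counts taken by abundant genes are argued against by a ratio of medians, meiocytes over other tissues, of 0.514 without the 100 most abundant genes (0.488 with them). Few RNA molecules sampled per library may be a cause. Of gene and library pairs with 20 or more thinned counts, 6.02% were at 0 in both other libraries of the stage, against 0.0302% in the other tissues. By stage the share ran from 0.568% in metaphase I to 12.9% in metaphase II. The metaphase II libraries differed least in the number of genes detected (SD 803), though r between them was 0.676 to 0.684. Differences between the cells collected for each library stay open and were not tested.

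Expression in ph1b pollen shifted broadly. Abundant genes taking the counts cannot be told apart by the 10525 genes called without the 100 most abundant ones, though the bound written beforehand against it was met, since TMM scaling already takes out such a shift (median log2 of all tested genes 0.104), which was noticed only afterwards. In CPM without TMM against Chinese Spring 2 and 3 (library 1 and anther chose the gene sets), genes at least 16-fold higher in anther rose by a median log2 of 1.316, past the bound of 1 written beforehand for anther RNA, but other expressed genes rose by 1.264 and all expressed genes by 1.444, a rise that depends on the scale, so the bound decided nothing; a margin over other genes was required only after this was seen, and some anther RNA cannot be told apart. As the whole cause, RNA like that of the sampled anthers is argued against. The counts allow 10.8% of it (10.4 to 11.4% over the libraries), and the fall of pollen genes from those 2 libraries needs 56.6% (51.5 to 63.7%). The sampled anthers had 0.25% of their counts in pollen genes. Anther tissue with other RNA than theirs is not covered by this bound. Again in CPM without TMM against these 2, genes at least 16-fold higher in pollen fell by a median log2 of -1.121, from 63.4% of their pooled counts (56.7% in library 1) to 27.7%, which is consistent with a different stage of pollen development, as a hypothesis; an effect of the genotype stays open.

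Other splits of the libraries were counted for each result. Changes across stages gave 561 genes (highest other split 187). The lowest other split still gave 73, so this test also called genes when the stage labels were shuffled. Meiocytes gave 28607 against leaf (8454), 24428 against flag leaf (7435), 21736 against anther (2850) and 27381 against pollen (10832). Each was reached by 1 of 25 splits, the real one, which is under 0.05 and the smallest share 25 splits can give. Genes higher in meiocytes than in all 4 tissues gave 103 (highest other 0, 1 of 21 splits). Those splits mixed meiocytes and tissues over the groups, so a count near 0 was likely from the start and decides nothing. The split counts for meiocytes against tissues used the contrast found faulty on simulated counts.

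Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05, since the smallest is 0.1. Leptotene against pre-meiotic G2 gave 51 genes and the highest other split 99 (7 splits as large), zygotene against leptotene 28 and 144 (4), pachytene against zygotene 9 and 25 (8), diplotene/diakinesis against pachytene 40 and 25 (1) and metaphase I against diplotene/diakinesis 23 and 26 (2). Metaphase II gave 62 against metaphase I with 18 as the highest other (1) and 206 against pre-meiotic G2 with 27 (1). The 144 of zygotene and leptotene, several times the real count, points to structure among those libraries other than stage. Flag leaf against leaf (237), pollen against anther (7452) and ph1b in leaf (885), flag leaf (478), anther (459) and pollen (10077) had 0 as the highest other split in edgeR and 1 split as large, the real one.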
